A study of Rattus norvegicus with 4 samples.

How the data were processed

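Rat neural stem/progenitor cells (NSPCs) were profiled in 4 libraries, 1 for each combination of platform (bare PUCL or PUCL@CNT1) and culture stage. Per the labels' protocols, cells were kept for 24 h in a stemness-maintaining medium (knockout DMEM/F12 with a neural supplement), called maintenance medium here. The other cells then went on for 1.5 d in B-27 Plus neuronal culture medium, called differentiation medium here, so medium and time in culture changed together. Per the labels' protocols, RNA was taken with Trizol and 500 ng of total RNA per library went into a Lexogen QuantSeq kit, which reads the 3' ends of polyadenylated transcripts.

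The deposited values were raw counts per gene symbol, with no normalization, as whole numbers that summed to a different total in each library. Per the submitters' processing notes, Bowtie2, bedtools and the rn6 genome build were used. No versions, annotation, strand setting, trimming, duplicate handling or filters were given in the sources used here. Antisense and overlapping genes could therefore not be told apart, and reads of near-identical gene copies may have been split. The tables held 17048 gene entries for 16881 symbols. For 149 symbols there were several entries, 316 in all, and their counts were summed; 74 of these symbols had counts, and their values (Eno2 and Actg1 among them) are uncertain. Of the symbols, 14393 matched a current RefSeq symbol (GRCr8 assembly), 2096 an older symbol and 392 neither; that reference was used for names and gene lengths only. The ribosomal RNA entries (Rn45s, Rn28s, Rn18s) overlap, since Rn45s held nearly the sum of the other 2 in each library.

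Of the symbols, 11199 had a count in any library and 5682 had none. Genes with 10 or more counts in at least 1 library were kept, which left 10516 and removed 6365. Libraries were scaled by the trimmed mean of M values (TMM), with factors of 1.01 for PUCL in maintenance medium, 1.03 for PUCL@CNT1 in maintenance medium, 0.982 for PUCL in differentiation medium and 0.97 for PUCL@CNT1 in differentiation medium. Log2 ratios of single pairs of libraries used a prior count of 0.5. Intervals were exact 95% binomial (Clopper-Pearson) intervals of the ratio of 2 counts. A count of 0 was set at 3 counts per library for bounds, which is 0.461, 0.497, 0.456 and 0.438 CPM (counts scaled to a common library size) in the 4 libraries in that order. The reads carry no molecular identifiers, so intervals cover counting error only. A bound, given as at least so many fold, takes the count that is not 0 as it stands, without error. It also leaves out scatter between libraries, so it is not a lower limit on the true change.

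With 1 library per group, a pair of libraries was described by a rule of size: a scaled ratio of at least 2-fold whose nearer 95% bound lay beyond 1.5-fold. No p-value was made for such a pair, and each pair compares 2 libraries, not 2 conditions. The change of the platform difference between media was described by the same sizes, with a normal interval on the log scale after 0.5 was added to each count. A quasi-likelihood F test in edgeR was fitted over the 4 libraries with platform and medium as additive terms, which leaves 1 residual degree of freedom. Spread was also pooled across genes, with 87.2 prior degrees of freedom. Each p-value therefore rests mostly on the spread of other genes and little on the gene's own. The edgeR fit treats the 2 platforms as repeats of 1 medium change and the 2 media as repeats of 1 platform difference, so a change confined to 1 platform counts as spread. All adjusted p-values are from edgeR with Benjamini-Hochberg adjustment at a threshold of 0.05. Correlations between log2 ratios run across genes, which are not independent replicates.

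Before the data were examined, 33 gene lists were fixed with 730 entries, of which 675 were in the files, 7 of them under an older symbol. The lists were neural stem/progenitor, proneural and neuronal transcription factors, immature neuron structure, synapse and transmitter, voltage-gated channels, immediate early genes, astrocyte, oligodendrocyte lineage, cell cycle S phase, cell cycle G2/M, FGF and EGF (MAPK) response, Notch pathway, Wnt targets, BMP and TGF-beta response, YAP/TEAD targets, adhesion and actomyosin, extracellular matrix, axon guidance, cholesterol biosynthesis, glycolysis and hypoxia, oxidative phosphorylation, integrated stress response, endoplasmic reticulum stress, oxidative stress (NRF2) response, p53 and apoptosis, inflammation and interferon, microglia, endothelium, mural cells and fibroblasts, ependyma and choroid plexus, nuclear-encoded ribosomal proteins, mitochondrial transcripts and heat shock. The mitochondrial transcripts were absent from the files, so 32 lists had members. A list's median log2 ratio was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, for the 30 lists with 5 or more tested members. Counts of members adjusted over the list alone are given where they differ from those over all genes. These percentiles describe the libraries and are not p-values. Across the medium change on each platform and the platform difference in each medium, 120 list medians were placed. Of these, 32 lay outside the central 95% of random lists. A percentile just outside that range was therefore not rare in these libraries and is weak evidence by itself.

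The main tests, the size rule, the lists and the rule for naming genes were also set before the data were examined. The rule named the 10 highest and 10 lowest mean medium ratios among genes passing on both platforms, and the 8 highest and 8 lowest platform ratios in each medium. It also named 5 and 5 for the change of the platform difference, up to 4 members per list, and 10 marker genes in every case (Nes, Sox2, Pax6, Dcx, Tubb3, Map2, Gfap, S100b, Olig2 and Mki67). Members of the fixed lists that passed in edgeR are named beyond it. Genes outside it are said to have been chosen after their values were seen. Results of some genes that the rule names are not reported here.

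Set down in advance as other ways to run the tests were total counts or DESeq2 size factors in place of TMM, no filter or a minimum of 50 counts, a 99% interval, thinning to the shallowest library, a prior count of 5, DESeq2 and limma-voom in place of edgeR, the other factor left out, and each library left out in turn. Leaving out the ribosomal RNA entries, and keeping the 3619 genes with a mean of 300 counts or more, were added after the data were seen. The other tests in which a gene's call is said to hold are these with all 4 libraries kept, 9 at most and fewer where a gene had no adjusted p. The steps were tested on simulated counts with the real means, library sizes and fitted spread and seeded changes of 2-, 4- and 8-fold. On 9905 simulated genes, edgeR found 14.9% of 2-fold, 52.2% of 4-fold and 60.6% of 8-fold medium changes, with 3.4% of its calls false. On 9913 simulated genes, it found 6% of 2-fold, 43.3% of 4-fold and 59.1% of 8-fold platform differences, with 5.3% of its calls false. Simulated genes of like expression had the same spread, and none changed on a single platform or in a single medium. The shares of false calls therefore need not hold for the real libraries. The work used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.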

Results

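Rat neural stem/progenitor cells (NSPCs) were compared on 2 culture platforms, bare PUCL and PUCL@CNT1, before and after a switch from stemness-maintaining medium to neuronal differentiation medium. No group had replicates: each of the 4 combinations was 1 library. Libraries held 6502918 (PUCL) and 6035848 (PUCL@CNT1) counts in maintenance medium, and 6580894 and 6855984 in differentiation medium, the order in which 4 counts of a gene are given. Between 9584 and 9842 symbols had a count per library, and 10516 genes were tested. The ribosomal RNA entries summed to 11.4% of counts on PUCL and 9.14% on PUCL@CNT1 in maintenance medium, and 13.4% and 8.49% in differentiation medium. They overlap, so these sums may count reads more than once. Rn45s alone held 5.66%, 4.54%, 6.72% and 4.25% in that order.

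Genes of cholesterol biosynthesis, which build sterols from acetyl-CoA, fell after the switch to differentiation medium. Hmgcs1, an early enzyme, had log2 ratios of -1.71 on PUCL and -1.32 on PUCL@CNT1 (edgeR adjusted p 6.85e-10). Msmo1 (fitted log2 -1.24, adjusted p 5.92e-07), Cyp51 (-1.14, 9.04e-06) and Fdps (-1.31, 0.000307), which act further along the pathway, fell too. Of 24 tested members, 13 fell in edgeR, 17 with p-values adjusted over the list alone, and 22 had ratios below 0 on both platforms. The list median was -1.41 on PUCL (percentile 0 among random lists) and -0.97 on PUCL@CNT1 (percentile 0). Acss2, which makes acetyl-CoA from acetate, had ratios of -2.74 and -3.09 (adjusted p 6.07e-11), and Tfrc, the iron uptake receptor, -2.06 and -1.78 (1.73e-07); both were chosen after their values were seen, as were Msmo1, Cyp51 and Fdps. The call of Fdps held in 8 of 9 other tests, and those of the other genes named in all 9.

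**Figure D1:**
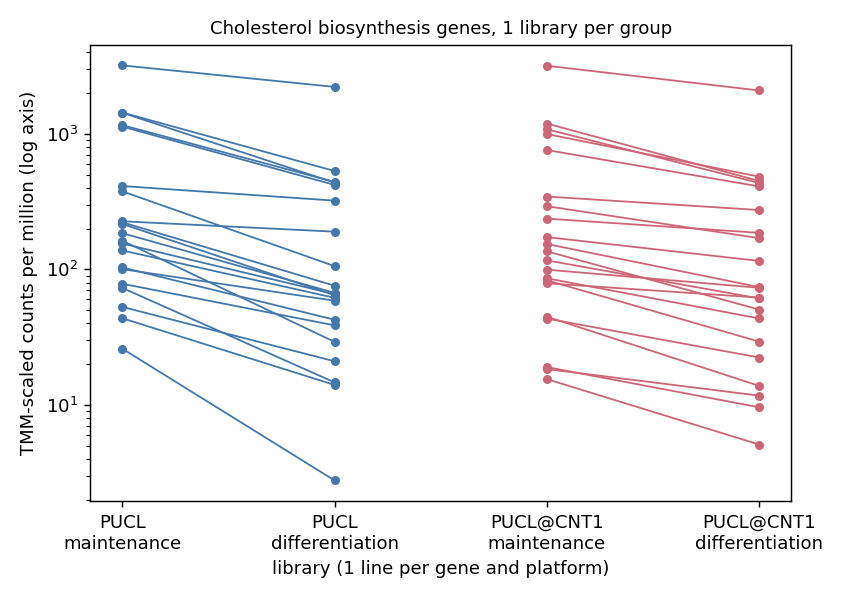
TMM-scaled CPM (log axis) of 21 cholesterol biosynthesis genes with counts in every library, with 1 line per gene and platform joining the media. Hmgcs1 had log2 ratios of -1.71 on PUCL and -1.32 on PUCL@CNT1 between media.

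Single genes with small adjusted p-values rose after the switch, and those given here except Mmp11 were chosen after their values were seen. Ucp2, a mitochondrial carrier, had log2 ratios of 4.40 on PUCL and 4.24 on PUCL@CNT1 (edgeR adjusted p 1.19e-16). Crym, which binds thyroid hormone, had 3.66 and 2.36 (adjusted p 6.86e-16). Lgals1, a secreted galectin, had 1.47 and 2.04 (adjusted p 1.3e-09), and Igfbp5, which binds insulin-like growth factors, 0.81 and 2.77 (3.45e-08, against 0.379 in DESeq2 and 0.0746 in edgeR on genes with a mean of 300 counts or more). Mmp11, a matrix protease named by the rule, had 4.04 on PUCL and was at least 145-fold higher on PUCL@CNT1, with 0 counts in maintenance medium there (adjusted p 2.41e-10, against 0.195 in DESeq2 and 0.087 in limma-voom). In edgeR, 189 genes rose and 107 fell (296 of 10516), and 1273 had an unadjusted p under 0.05. The share that rose was 63.9%, and 53.5% under total counts in place of TMM. Leaving the platform term out of the fit gave 176 genes. With that term and the PUCL maintenance library both left out, 35 passed (88.6% higher), and with that term and the PUCL@CNT1 maintenance library left out, 25 (60%). Without that term and the PUCL@CNT1 differentiation library more genes were lower (144) than higher (119), so the balance of rises and falls is not settled. Medium and 1.5 d of further culture changed together, so neither can be named alone.

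**Figure D2:**
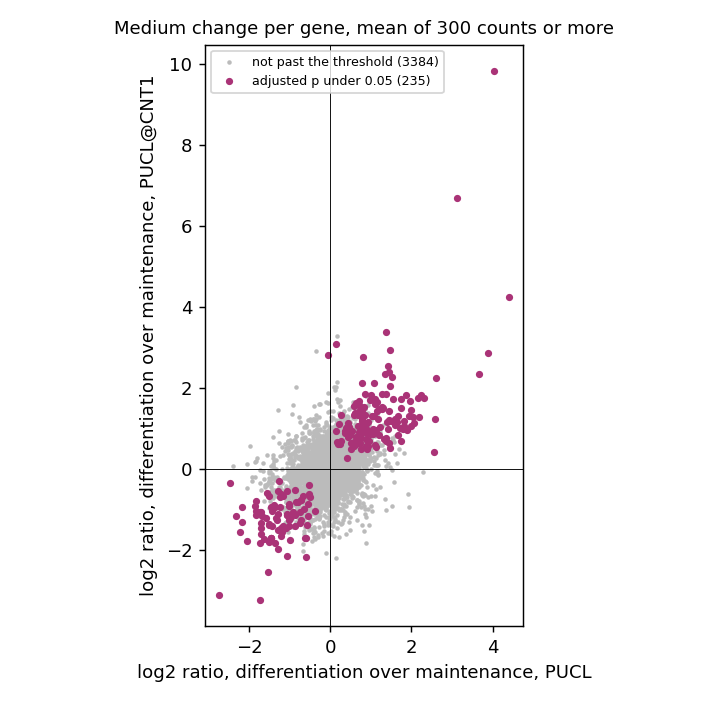
Log2 ratio between media on PUCL (horizontal) and PUCL@CNT1 (vertical) for 3619 genes with a mean of 300 counts or more. Coloured points are the 235 genes that passed in edgeR in the fit over all 10516 genes, a test that itself favours genes with like changes on both platforms; a fit on these 3619 genes alone passed 28.

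Neural stem and progenitor genes did not go down as a group after the switch. The list holds markers as well as regulators, and some, such as Slc1a3, are also genes of astrocytes. The list median log2 ratio was 0.58 on PUCL (percentile 100) and 0.42 on PUCL@CNT1 (percentile 97.3), and 4 of 16 rose (6 adjusted over the list alone). Hes1, a Notch effector that represses neuronal fate, rose by a fitted log2 of 1.37 (SE 0.345, adjusted p 0.0103). Fabp7, the radial glia lipid carrier, rose by 0.88 (SE 0.174, adjusted p 0.000491), and the filament gene Vim by 0.41 (SE 0.119, adjusted p 0.0321). Cdh2, the N-cadherin of neuroepithelium, rose by 0.93 (SE 0.247, adjusted p 0.0164); Fabp7, Vim and Cdh2 were chosen after their values were seen. Nes had ratios of 0.55 and 0.56 (adjusted p 0.133) and Sox2 0.61 and -0.13 (0.766), both outside the threshold. Pax6, at 53, 21, 246 and 19 counts, had 2.23 on PUCL and -0.23 on PUCL@CNT1 (adjusted p 0.889). Calls held in 9 of 9 other tests for Fabp7, 7 for Hes1, 5 for Cdh2 and 2 for Vim.

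Neuronal genes did not move as a group after the switch. Proneural and neuronal transcription factors had medians of 0.06 on PUCL (percentile 66.6) and 0.00 on PUCL@CNT1 (percentile 51.5), and Pou3f2, which drives neuronal fate, rose (log2 1.28 and 1.54, adjusted p 0.00981), the only one of 10. Among 26 genes of immature neuron structure (-0.15, percentile 24.2, and 0.22, percentile 83.5), 2 rose and 1 fell (3 and 3 adjusted over the list alone). Tagln3, a neuronal actin-binding protein, rose by log2 4.42 on PUCL and at least 36-fold on PUCL@CNT1 (17, 0, 367 and 115 counts, adjusted p 5.57e-05), and Cd24 rose by 0.96 (0.0164). Mllt11 fell (fitted log2 -1.39, adjusted p 0.019); Cd24 and Mllt11 were chosen after their values were seen. Dcx, the migrating neuroblast marker, stood at 48, 39, 79 and 61 counts, and Tubb3 at 28, 20, 25 and 62. Map2, a dendrite marker, had -0.41 and -1.46 (adjusted p 0.215). Other tests kept the call of Tagln3 in 7 of 8, and in 9 tests that of Pou3f2 in 7, Mllt11 in 6 and Cd24 in 5.

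Synapse and channel genes carry mature neuronal signalling, and few of them passed in edgeR after the switch. The 23 synapse and transmitter genes had medians of 0.00 on PUCL (percentile 47.3) and -0.52 on PUCL@CNT1 (percentile 1.51). Among them 2 fell, and Dlg4, the postsynaptic scaffold, did so by a fitted log2 of -0.69 (edgeR adjusted p 0.0116). The 19 voltage-gated channels had medians of 0.00 (percentile 43.2) and 0.03 (percentile 58.4), with 0 past the edgeR threshold and 3 higher and 0 lower on both platforms by the size rule; Kcnd3 had 1.19 and 2.09 (adjusted p 0.101). Among 21 immediate early genes, which follow activity, medians were -0.08 (percentile 30) and 0.17 (percentile 79.8), and Arc fell by a fitted log2 of -1.09 (adjusted p 0.0156); Dlg4 and Arc were chosen after their values were seen. Axon guidance genes (17) had medians of 0.55 (percentile 90.2) and 0.66 (percentile 92.1), with 0 past the threshold. The call of Dlg4 held in 6 of 9 other tests and that of Arc in 5.

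Glial genes were higher after the switch, those of astrocytes on PUCL and those of the oligodendrocyte lineage on both platforms. The 17 astrocyte genes had medians of 1.28 on PUCL (percentile 100) and 0.00 on PUCL@CNT1 (percentile 42.6). Clu, a secreted chaperone of astrocytes, rose (log2 1.96 and 1.69, adjusted p 0.000501; 3 members did, 4 adjusted over the list alone), as did the protease inhibitor Cst3 (0.90 and 0.97, 2.61e-09, chosen after its values were seen). S100b, the calcium-binding glial marker, also rose, with 2.56 on PUCL and 0.42 on PUCL@CNT1 (adjusted p 0.000279). Gfap stood at 0, 19, 31 and 0 counts. By bounds that leave out scatter between libraries, it was at least 10.5-fold higher on PUCL and at least 6.74-fold lower on PUCL@CNT1. The 15 oligodendrocyte lineage genes had medians of 0.80 (percentile 99.8) and 0.65 (percentile 99.2), and 4 rose (6 adjusted over the list alone). Olig1 (1.17 and 1.23, adjusted p 1.92e-05), the myelin genes Cnp (1.42 and 1.00, 0.0117) and Mbp (fitted 1.03, 0.0227, chosen after its values were seen) rose, while Olig2 had 0.07 and 0.48 (0.745). Of 9 other tests, all kept the calls of Cst3 and Olig1, 8 that of Clu, 7 that of S100b, 6 that of Cnp and 5 that of Mbp.

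Cell cycle genes had low medians among random lists after the switch on PUCL@CNT1, but not on PUCL. No S phase or G2/M member passed the edgeR threshold. That fit counts a change confined to 1 platform as spread, so it cannot decide whether these genes fell on PUCL@CNT1 alone. S phase genes (22), which copy DNA, had medians of 0.14 on PUCL (percentile 88.8) and -0.54 on PUCL@CNT1 (percentile 0.11), with 0 past the threshold. The 21 G2/M genes of mitosis had -0.10 (percentile 28.1) and -0.52 (percentile 0.02), with 0 past it. Mki67, the division marker, had 0.04 and -1.02 (adjusted p 0.63). Growth factor response genes (19, FGF and EGF) had medians of -0.34 (percentile 2.26) and -0.02 (percentile 24.5), with 0 past it (1 higher and 2 lower adjusted over the list alone), and Dusp6, a feedback phosphatase, had -0.61 and -0.25 (adjusted p 0.121).

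Among signalling lists, the Notch pathway medians lay above the central 95% of random lists after the switch. The Wnt, BMP and YAP/TEAD medians lay within it. The 12 Notch pathway genes, which hold progenitors back from differentiation, had medians of 1.55 on PUCL (percentile 99.8) and 0.98 on PUCL@CNT1 (percentile 97.8). With zeros at the floor the PUCL@CNT1 median was 0.60, for which no percentile was made. In edgeR Hes1 was the member that rose (2 members adjusted over the list alone). By the size rule 3 members were higher and 1 lower on both platforms. Hes1, Hes5, Notch1 and Notch2 are also in the stem and progenitor list, so these lists are not separate. Wnt targets (7) had 0.00 (percentile 53.9) and 0.70 (percentile 92.6), with 0 past the threshold (1 adjusted over the list alone), and Dkk3, a secreted Wnt modulator, had a fitted 2.49 (adjusted p 0.0834). BMP and TGF-beta response genes (14) had 0.12 (percentile 72.7) and 0.25 (percentile 77.8), and Id2, an inhibitor of proneural factors, rose (1.48 and 3.17, adjusted p 0.0123). The YAP/TEAD list (13 genes) holds Yap1, Wwtr1 and Tead1 themselves beside targets, so its medians do not read targets alone. It had 0.00 (percentile 49.1) and 0.43 (percentile 86.5), with 0 past the threshold. The target Cyr61 had -1.71 and -1.38 (adjusted p 0.125). The call of Hes1 held in 7 of 9 other tests and that of Id2 in 5 of 8.

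Adhesion, contractile and matrix genes changed one by one. Among 26 adhesion and actomyosin genes (medians -0.21, percentile 6.28, and 0.13, percentile 76.9), 3 rose and 2 fell (4 and 3 adjusted over the list alone). Myl9, a myosin light chain, rose (log2 2.28 and 4.21, adjusted p 0.000336), as did the integrins Itgb5 (1.41 and 2.55, 0.000723) and Itga7 (2.54 and 1.91, 0.0127). Acta2, the smooth muscle actin, fell (-1.07 and -1.12, adjusted p 1.96e-05), and so did the integrin Itga6 (fitted -1.17, 0.00292). Extracellular matrix genes (22) had medians of 0.18 (percentile 80) and 0.39 (percentile 92.1), with the protease Mmp2 (5.01 and 2.68, adjusted p 0.00903) and Sparc (fitted 0.82, 0.0036) the 2 that rose (3 adjusted over the list alone). Itga6 and Sparc were chosen after their values were seen. Of 9 other tests, all kept the call of Acta2, 8 that of Itga6, and 7 those of Itgb5 and Sparc. Of 8 other tests, 7 kept the call of Myl9 and 6 those of Itga7 and Mmp2.

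Energy metabolism and ribosomal protein lists had 1 or 2 members past the threshold each. Among 23 glycolysis and hypoxia genes, Vegfa, the vessel growth factor, fell (log2 -1.31 and -2.27, adjusted p 0.0227, past the threshold in 4 of 8 other tests), and so did P4ha1, for collagen hydroxylation (-1.58 and -1.22, 0.0151). That list had medians of -0.35 on PUCL (percentile 1.68) and 0.37 on PUCL@CNT1 (percentile 96.6), and 3 members fell when adjusted over the list alone. Oxidative phosphorylation genes (25) had 0.25 (percentile 98.8) and 0.14 (percentile 71.1), and Ndufa4, a respiratory chain subunit, rose (0.62 and 0.80, adjusted p 0.00289), with 4 members higher when adjusted over the list alone. The ribosomal protein list (26 genes, 2 of them elongation factors) had -0.01 (percentile 30.3) and 0.19 (percentile 77.2), with Rplp1 rising (0.63 and 0.65, adjusted p 0.00141). Ndufa4 and Rplp1 kept their calls in 7 of 9 other tests, and P4ha1 in 6.

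Stress response lists had few members past the threshold after the switch. In the integrated stress response list (21 genes, medians 0.13, percentile 82.2, and 0.23, percentile 86.3), Ddit4, an mTOR inhibitor, rose (log2 1.53 and 2.27, adjusted p 5.88e-07), as did Slc7a11, the cystine importer (2.31 and 1.75, 0.00107); 2 more fell when adjusted over the list alone. Oxidative stress genes (21) had 0.11 (percentile 81.5) and 0.27 (percentile 92.6); Fth1, the ferritin chain, rose by 0.62 (adjusted p 0.00482; 3 members rose, 4 adjusted over the list alone), while Hmox1, which degrades heme, fell by a fitted -0.99 (0.00485). Heat shock genes (13) had -0.08 (percentile 31.4) and 0.30 (percentile 88.8), and the chaperones Cryab (1.69 and 2.23, adjusted p 0.00456) and Hspb1 (1.66 and 1.30, 0.0136) rose. Endoplasmic reticulum stress genes (18) had 0.15 (percentile 84.6) and 0.19 (percentile 81.6), with 0 past the threshold, and the chaperone Hspa5 had -0.03 and -0.26 (adjusted p 0.896). In the p53 and apoptosis list (15 genes, 0.16, percentile 82.3, and 0.67, percentile 99.5), Ccng1 rose by 0.95 (adjusted p 0.0105) and Cdkn1a, the cell cycle inhibitor, by 0.69 (0.0498, but up to 0.163 under other tests, with 1 of 9 past the threshold), with 3 higher when adjusted over the list alone. Inflammation and interferon genes (13) had 0.19 (percentile 76.5) and 1.05 (percentile 97.3), with B2m, of antigen presentation, rising by 0.95 (adjusted p 0.000344). Fth1, Hmox1, Ccng1, Cdkn1a and B2m were chosen after their values were seen. Of 9 other tests, all kept the calls of Ddit4 and B2m, 8 those of Slc7a11 and Hmox1, 7 that of Fth1, and 6 those of Hspb1 and Ccng1; Cryab kept its call in 8 of 8.

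Genes of other cell types had few members past the threshold. The 9 endothelial genes had medians of 2.95 on PUCL (percentile 99.4; 2.61 with zeros at the floor) and 0.00 on PUCL@CNT1 (percentile 41.2), with 0 past the threshold. Flt1, a vessel receptor, stood at 0, 24, 18 and 125 counts. The 10 mural cell and fibroblast genes had -2.52 (percentile 0.27; -1.64 with zeros at the floor) and 0.14 (percentile 61.2), and Acta2 was the member that fell. Only 4 microglia genes and 4 ependyma and choroid plexus genes were tested, with 0 past the threshold; Cd14 stood at 21, 28, 83 and 51 counts and Foxj1 at 45, 0, 123 and 35.

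The largest medium ratios on both platforms were in genes with 0 counts in 1 medium. Prrg4, a membrane protein, was at least 14.3-fold higher on PUCL and at least 105-fold higher on PUCL@CNT1 (edgeR adjusted p 2.29e-05). Pc, the pyruvate carboxylase, was at least 53-fold and 18.8-fold higher (adjusted p 0.0123), Manba, a lysosomal mannosidase, 58.5-fold and 16-fold (0.01), and Acad11, for fatty acid oxidation, 23.5-fold and 34.1-fold (0.0463, but up to 0.162 under other tests). Sult5a1, a sulfotransferase, was at least 77.8-fold and 63.1-fold lower (adjusted p 4.03e-07), with Pdia5, a protein folding enzyme, at 42.1-fold and 17-fold (0.0473, but up to 0.172 under other tests). Ankle2, of the nuclear envelope, was at least 63.7-fold and 4.97-fold lower (adjusted p 0.0297). The genes given here are ones that passed in edgeR, and not every gene that the rule named for the medium change did. Calls held in 6 of 8 other tests for Prrg4, Pc, Manba and Sult5a1, in 5 for Ankle2 (up to 0.251) and in 3 for Acad11 and Pdia5.

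Many genes passed the size rule between single libraries, and fewer did so on both platforms. On PUCL, 1689 genes were higher and 1605 lower in differentiation medium (31.3% of those tested), and on PUCL@CNT1 1736 and 1522 (31%). On both platforms, 457 were higher and 371 lower, where independent lists would share 279 and 232, and 441 had opposite directions (509). Of the unchanged genes in simulated libraries, 27.4% passed in 1 pair and 5.47% in both. Among the 3619 genes of higher counts, 62 were higher and 54 lower on both, and 3 were opposite (8.1, 11.2 and 19.4 for independent lists). The correlation of medium ratios between platforms was 0.08 (Spearman 0.162) over all genes and 0.702 over those with means above 3000 counts. Platform ratios in maintenance medium had an SD across genes of 2.32 at 30 to 100 counts and 0.291 above 3000 counts.

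**Figure D3:**
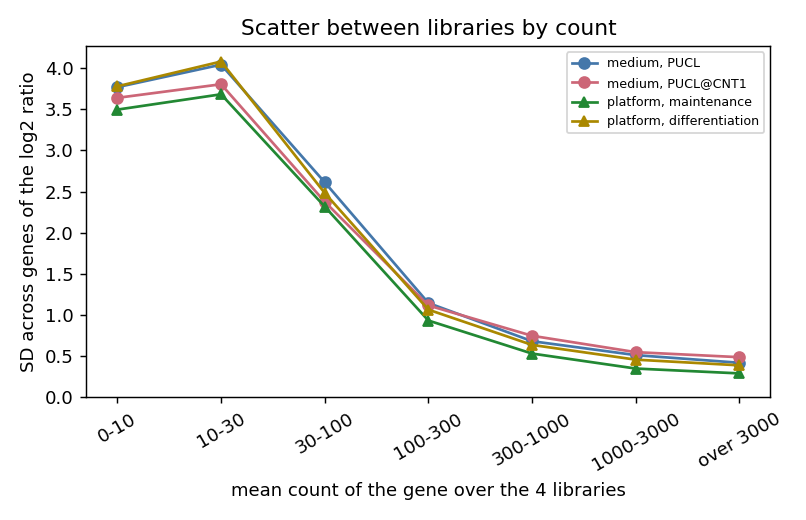
SD across genes of the log2 ratio (vertical) by bin of mean count (horizontal) for the 4 pairs of libraries. In maintenance medium the platform SD was 2.32 at 30 to 100 counts and 0.291 above 3000 counts.

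Single genes of stress responses and growth arrest were higher on PUCL@CNT1 than on PUCL. Hmox1, which degrades heme under oxidative stress, had log2 ratios of 1.53 in maintenance and 1.01 in differentiation medium (edgeR adjusted p 0.000622). Hspa1b, the inducible HSP70 chaperone, had 2.18 and 2.48 (adjusted p 0.000991), and Adm, a hypoxia-induced peptide, 1.36 and 1.11 (0.000325). Cdkn1a, a p53 target that stops the cell cycle, had 0.69 and 1.32 (adjusted p 0.0056), and Ccng1, another p53 target, was higher by a fitted 0.93 (0.0459). Dolk, of protein glycosylation, had 3.69 and 2.53 (adjusted p 0.0102), and the mitochondrial chaperone Hspe1 was higher by 0.69 (0.0459); Dolk, Ccng1, Cdkn1a and Hspe1 were chosen after their values were seen. In edgeR 22 genes were higher and 26 lower (48 of 10516, 731 with an unadjusted p under 0.05), against 38 in DESeq2 (23 higher, 15 lower, 23 among the 48) and 87 in limma-voom (50 higher, 37 lower, 38 among the 48). Within edgeR, DESeq2 size factors gave 18 genes (6 higher, 12 lower), total counts 27 and no filter 25. A minimum of 50 counts gave 10 (3 higher, 7 lower) and a mean of 300 counts 0. Leaving the medium term out of edgeR, with all 4 libraries kept, gave 0 genes (388 with an unadjusted p under 0.05), so every call named here rests on that term. With that term and 1 library left out, the count was 0 without the PUCL library of differentiation medium (356) and 1 without that of maintenance medium (566). Without the PUCL@CNT1 library of maintenance medium it was 24 (544), of which 8 were among the 48, and without that of differentiation medium 27 (480), of which 14 were. Of 9 other tests, 7 kept the calls of Hmox1 and Adm, 6 that of Cdkn1a, and 3 those of Ccng1 and Hspe1. For Hspa1b it was 6 of 8, and for Dolk 4 of 7.

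Single genes of astroglia and other functions were lower on PUCL@CNT1, by calls that ended when the medium term was left out of edgeR (0 genes, 388 with an unadjusted p under 0.05). Cst3 had log2 ratios of -0.74 in maintenance and -0.68 in differentiation medium (edgeR adjusted p 5.02e-05), and S100b -0.28 and -2.41 (0.00578). Slc1a3, the glutamate transporter of radial glia and astrocytes, was lower by a fitted -0.82 (adjusted p 0.0457), and Ptprz1, a progenitor phosphatase, had -0.38 and -1.37 (0.0256, past the threshold in 3 of 9 other tests). Itgb5, an integrin for vitronectin, had -2.90 and -1.76 (adjusted p 0.000252), and Id1, a BMP target, a fitted -1.06 (0.0429). Slc1a3, Id1 and Cst3 were chosen after their values were seen, as were the following. Nrgn, a calmodulin-binding protein, had -1.30 and -0.48 (adjusted p 5.02e-05), the bicarbonate transporter Slc4a4 -1.49 and -2.10 (0.000325) and the collagen Col5a3 -1.08 and -1.76 (0.0056). The ribosomal RNA entries Rn18s (fitted -0.63, adjusted p 9.46e-07) and Rn28s (-0.42, 0.000622) were lower as well. Summed over all ribosomal RNA entries, which overlap, the shares were 9.14% against 11.4% and 8.49% against 13.4%. Of 9 other tests, 7 kept the calls of Cst3 and Nrgn, 5 that of S100b and 3 that of Slc1a3. Of 8 other tests, 6 kept the calls of Itgb5, Slc4a4, Rn18s and Rn28s, 5 that of Col5a3 and 2 that of Id1.

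**Figure D4:**
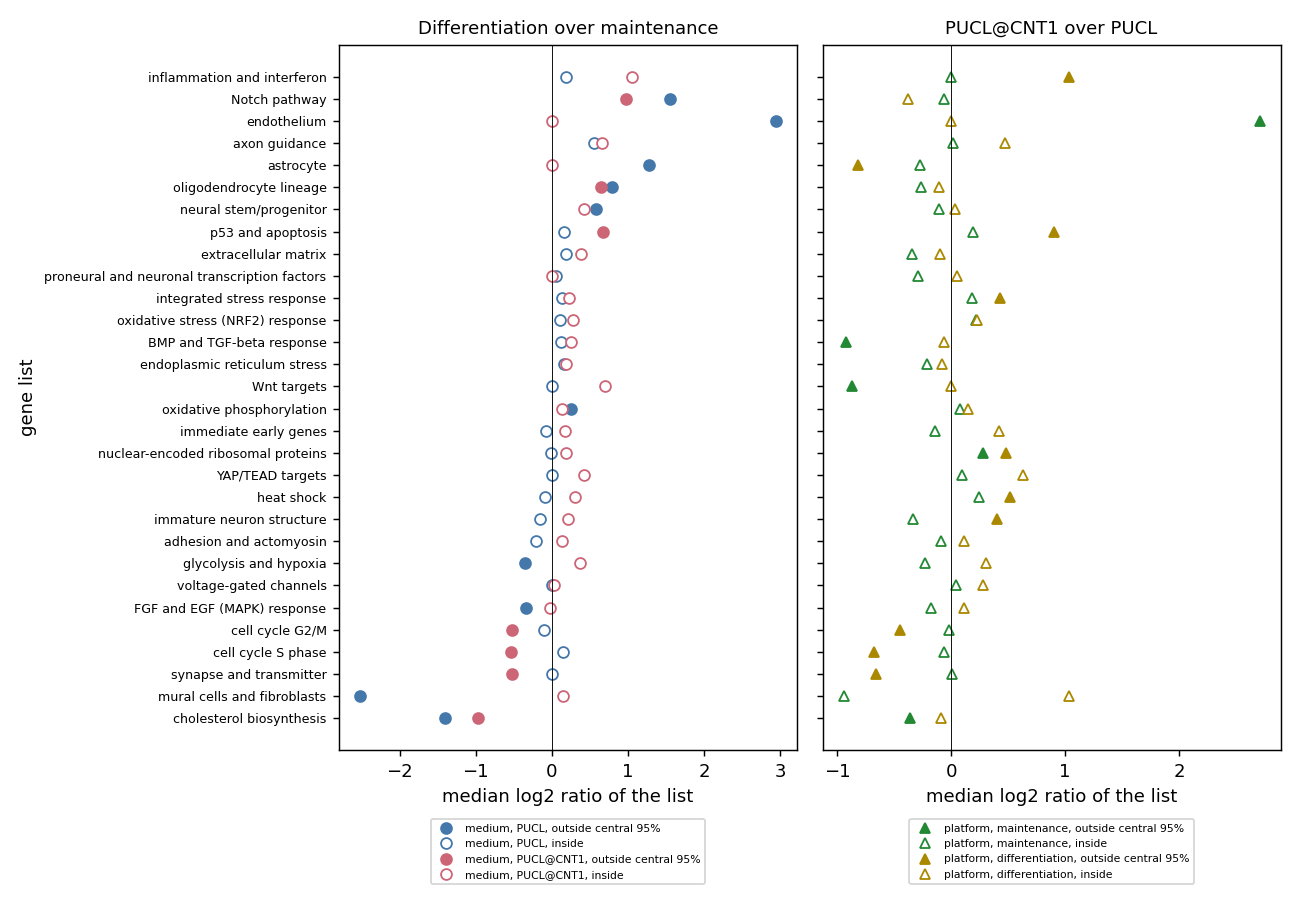
Median log2 ratio of 30 gene lists for the medium change (left) and the platform difference (right), with filled marks outside the central 95% of random lists. Cholesterol biosynthesis lay at -1.41 on PUCL between media.

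Ribosomal protein genes, which build ribosomes, were slightly higher on PUCL@CNT1, and cell cycle and astrocyte genes were lower there in differentiation medium. The list of 26, which holds the elongation factors Eef1a1 and Eef2 beside ribosomal protein genes, had medians of 0.28 in maintenance (percentile 100) and 0.48 in differentiation medium (percentile 100), with 24 higher in both; Rps6, chosen after its values were seen, passed in edgeR (fitted 0.66, adjusted p 0.0258, and in 4 of 9 other tests), and 12 did when adjusted over the list alone. Summed shares of the overlapping ribosomal RNA entries were lower on PUCL@CNT1 in both media, at 9.14% against 11.4% and at 8.49% against 13.4%. S phase genes had medians of -0.07 (percentile 31.4) and -0.68 (percentile 0), with 0 past the threshold and 4 lower when adjusted over the list alone; Mcm5, a replication helicase subunit, had -1.62 and -2.32 (adjusted p 0.0533). G2/M genes had -0.02 (percentile 40.2) and -0.45 (percentile 0.04), with 3 lower when adjusted over the list alone. Astrocyte genes had -0.28 (percentile 3.38) and -0.81 (percentile 0.01), and 3 were lower in edgeR (5 lower and 1 higher adjusted over the list alone). Genes of p53 and apoptosis had 0.19 (percentile 89.6) and 0.90 (percentile 100), with 2 higher in edgeR. Heat shock genes had 0.24 (percentile 93.9) and 0.52 (percentile 99.2), with 2 higher in edgeR (3 adjusted over the list alone). Oxidative stress genes had 0.22 (percentile 96.9) and 0.23 (percentile 87.5), with 1 higher (2 adjusted over the list alone).

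Neuronal lists did not share 1 direction between platforms. Immature neuron structure genes had medians of -0.33 in maintenance (percentile 3.89) and 0.41 in differentiation medium (percentile 97.6), with 0 past the edgeR threshold; Celf4, an RNA-binding protein of neurons, was at least 13.9-fold higher on PUCL@CNT1 in differentiation medium. Synapse and transmitter genes had 0.01 (percentile 68.5) and -0.66 (percentile 0.46), with 0 past it; Snap25, for vesicle fusion, had -2.67 and was at least 17.1-fold lower. Proneural factors had -0.29 (percentile 11.6) and 0.05 (percentile 60.2), with 0 past the threshold and 1 lower when adjusted over the list alone. Channels had 0.04 (percentile 73.8) and 0.28 (percentile 80.9), immediate early genes -0.14 (percentile 18.2) and 0.42 (percentile 97.4), and axon guidance genes 0.02 (percentile 66.7) and 0.47 (percentile 90.1). Fosl1, an activity-regulated factor, had 1.96 and 1.03 (adjusted p 0.326). Stem and progenitor genes had -0.11 (percentile 15.3) and 0.03 (percentile 37.1), with 2 lower in edgeR (2 lower and 1 higher adjusted over the list alone), and oligodendrocyte genes -0.27 (percentile 7.72) and -0.10 (percentile 23).

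Signalling and matrix lists, which cover fate signals and the cells' surroundings, had few members past the threshold between platforms. BMP and TGF-beta response genes had medians of -0.92 (percentile 0.96; -0.73 with zeros at the floor) and -0.06 (percentile 31.4), with Id1 the member lower in edgeR (and in 2 of 8 other tests; 2 adjusted over the list alone). Wnt targets had -0.87 (percentile 2.02) and 0.00 (percentile 48.9), Notch genes -0.06 (percentile 34.5) and -0.38 (percentile 9.83), and growth factor response genes -0.17 (percentile 8.21) and 0.12 (percentile 64.8). Phlda1, of that last list, was higher by a fitted 0.79 (adjusted p 0.0457, past the threshold in 3 of 9 other tests; 3 members adjusted over the list alone) and was chosen after its values were seen. The YAP/TEAD list had 0.09 (percentile 69.7) and 0.63 (percentile 96.5), adhesion genes -0.09 (percentile 16.9) and 0.11 (percentile 63.4), and matrix genes -0.34 (percentile 2.74) and -0.09 (percentile 26.9). Wwtr1, the TAZ coactivator, had 0.17 and 1.92 (adjusted p 0.476), and Tead1, its DNA-binding partner, -0.40 and -2.02 (0.984).

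Metabolic and remaining lists were mixed between platforms. Cholesterol biosynthesis genes had medians of -0.36 in maintenance (percentile 0.09) and -0.09 in differentiation medium (percentile 12.3), with Mvk, an early enzyme, at -1.52 and -0.84 (adjusted p 0.748). Glycolysis and hypoxia genes had -0.23 (percentile 3.77) and 0.31 (percentile 94.9), and oxidative phosphorylation genes 0.07 (percentile 74.5) and 0.15 (percentile 70). Integrated stress response genes had 0.19 (percentile 92.8) and 0.42 (percentile 98.8), with Sesn2, a nutrient sensor, at 1.48 and 0.60 (adjusted p 0.794), and 1 higher and 1 lower when adjusted over the list alone. Endoplasmic reticulum stress genes had -0.21 (percentile 3.57) and -0.08 (percentile 20.6), and inflammation genes 0.00 (percentile 51.7) and 1.03 (percentile 97.9). Endothelial genes had 2.71 (percentile 99.6; 1.81 with zeros at the floor) and 0.00 (percentile 48.9), and mural genes -0.94 (percentile 2.99) and 1.03 (percentile 96.7; 0.73 with zeros at the floor).

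Many of the largest platform ratios were again in genes with 0 counts in a library. Celf2, an RNA-binding protein, was at least 49.6-fold higher on PUCL@CNT1 in maintenance and at least 13.3-fold in differentiation medium (0, 141, 0 and 41 counts). Ttll1, a tubulin-modifying enzyme, was at least 16.5-fold and 65.5-fold higher (edgeR adjusted p 0.0186, past the threshold in 3 of 7 other tests). Elmo3, an engulfment adaptor, was at least 36.9-fold and 18.5-fold lower (117, 0, 54 and 0 counts). Other genes that the rule named went opposite ways in the 2 media, among them Rgs2 (0, 135, 15 and 0 counts) and Snx13 (101, 0, 0 and 8 counts). By the size rule 1278 genes were higher and 1466 lower in maintenance medium (26.1% of those tested), and 1598 and 1640 in differentiation medium (30.8%). In both media, 265 were higher and 333 lower, where independent lists would share 194 and 229, and 524 were opposite (422). Of unchanged genes in simulated libraries, 27.1% passed in 1 pair and 5.67% in both. The 598 of 10516 real genes that passed the same way in both media were close to that last share. Their number is therefore no evidence of platform differences shared between media. Ratios in the 2 media had a correlation of 0.02 (Spearman 0.055), and 0.481 above 3000 counts.

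The rule for the change of the platform difference between media named genes with 0 counts in 2 of the 4 libraries. Usp51, a deubiquitinase, stood at 117, 0, 0 and 70 counts: at least 36.9-fold lower on PUCL@CNT1 in maintenance and at least 22.7-fold higher in differentiation medium. Mpped2, a metallophosphoesterase, was at least 27.5-fold lower and then 20.4-fold higher, and Bdh1, for ketone body use, 21.5-fold lower and then 18.5-fold higher. Dcaf17, a ubiquitin ligase adaptor, was at least 26.7-fold higher in maintenance and 29.1-fold lower in differentiation medium, and Pclo, a presynaptic scaffold, 23.2-fold higher and then 18.5-fold lower. By the size rule the difference was higher in differentiation medium for 1618 genes and lower for 1483 (29.5% of those tested). With 1 library per group this change had no test.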

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

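All tests of explanations below except those of gene length were chosen only after the result was seen.

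Values in this part are log2 platform differences (PUCL@CNT1 over PUCL) in differentiation medium minus those in maintenance medium, with zeros at 3 counts, for genes whose direction differed between groups and lists whose value lay outside the central 95% of random lists. Values are given for 32 such genes among 254 named ones, 29 of them with a library at 0 and none above 265 counts, and for 7 of 30 lists; no test was made of these values.

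The medium change was opposite on the 2 platforms for Bcorl1 (5.26), Tmem192 (5.67), Wdr73 (5.01), Xirp2 (6.39, 1 count on PUCL in differentiation medium), Kcnd2 (4.71) and Acaca (3.78). It was opposite the other way for Rom1 (-6.92, 1 count on PUCL@CNT1 in differentiation medium), Uhrf1 (-4.86), Stx1a (-4.66), Vstm2b (-4.33) and Zfp2 (-4.04). Counting intervals, with 0.5 added to each count, ran from 3.35 to 8.34 for Xirp2 and from -8.85 to -3.88 for Rom1.

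The platform difference went from lower to higher for Slc30a7 (10.05, 1 count on PUCL@CNT1 in maintenance medium), Usp51 (9.71), Prrg1 (9.40, 3 counts there), Mpped2 (9.13), Ropn1l (8.87), Tmem220 (8.68) and Bdh1 (8.63). Smaller values were those of Snx13 (6.37), Ncam1 (4.19) and Nkd1 (3.67). Counting intervals ran from 7.42 to 16.75 for Slc30a7 and from 7.30 to 10.91 for Prrg1.

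From higher to lower went Dcaf17 (-9.61), Pdk1 (-9.42), Pclo (-8.75), Adam4 (-8.64), Stxbp4 (-8.52), Cntrob (-8.41) and Kif28p (-8.18). So did Rgs2 (-7.93), Dlg3 (-7.23), Mapk4 (-7.10) and Gfap (-6.15).

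The medians of these lists need not have opposite signs in the 2 media. Those with higher values were immature neuron structure (0.79, percentile 99.5, 0.68 with zeros at the floor), p53 and apoptosis (0.69, percentile 99.2) and mural cells and fibroblasts (2.59, percentile 98.4, 2.40 with zeros at the floor). Lower were synapse and transmitter (-0.84, percentile 0.97), astrocyte (-0.77, percentile 0.3), cell cycle S phase (-0.58, percentile 0.06) and cell cycle G2/M (-0.39, percentile 0.14).

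Genes of 30 to 1000 mean counts scattered between libraries far beyond counting error, with variances 24.9, 28.4 and 36.5 times the counting variance in 3 bins of rising count, then 62.7 and 349 times above 1000 counts. The variances compare the platforms within each medium, so true platform differences count as scatter too. The bin of highest counts holds the ribosomal RNA entries, and their part in the slope over all bins was not separated. Few RNA molecules each read many times would give a constant ratio, and variation between cultures in proportion to expression a ratio rising with the count. The log-log slope was 0.174 (interval 0.146 to 0.203) over 30 to 1000 counts, nearer the former, but 0.521 over all bins, nearer the latter. A spread between cultures that falls with expression would look the same as few molecules, so 0.174 leaves both explanations open. Molecular identifiers or a repeat library from the same RNA would tell them apart.

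Cholesterol genes were lower after the switch on both platforms. Library scaling moved a ratio by at most 0.094 in log2, which is too small to be its cause. Scatter of single libraries gave at most 16 of 24 members lower on both platforms in 10000 random lists (7 in the median), against 22 observed. Scatter gene by gene is therefore unlikely as the cause. Random lists hold unrelated genes, so a difference between single cultures that moves these genes together was not tested and stays open. New medium and longer culture cannot be told apart, since 0 libraries separate them.

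Ribosomal protein genes were higher and cell cycle and astrocyte genes lower on PUCL@CNT1 in differentiation medium. Scaling shifts all genes alike and cannot make the difference of 1.16 between the medians of the ribosomal protein and S phase lists. Gene length is unlikely as the cause, since among random lists matched on length the percentiles were 99.9 (ribosomal proteins), 0 (S phase), 0.03 (G2/M) and 0.02 (astrocyte). Transcript length could not be checked, so an effect of it stays open. A difference between single cultures, in density or RNA quality, stays open with 1 library per group.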

How the results depend on the processing

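Keeping genes with a mean of 300 counts or more, and leaving out ribosomal RNA, were tests added after the data were seen; the others were planned.

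Libraries could not be paired by culture, because the groups share only replicate number 1. The additive fit did compare media within platforms and platforms within media. Under the 99% interval, thinning or no ribosomal RNA, no count by the size rule moved by more than 1.5 times. With a mean of 300 counts or more, the size rule gave 327 genes for the medium change on PUCL, 412 on PUCL@CNT1, 139 for the platform difference in maintenance and 303 in differentiation medium, and 426 for its change between media. On both platforms 113 passed, and in both media 18, with scaling recomputed on the 3619 genes; the correlations were 0.463 and 0.182. With 50 counts as the minimum they were 0.157 and 0.07, and with a prior count of 5 the medium correlation was 0.132. In edgeR the medium change gave 28 genes at a mean of 300 counts and 138 at 50 counts; the prior degrees of freedom (6.6 and 15.7, from 87.2), the number of genes and the spread all changed, and their parts in this were not separated. DESeq2 gave 170, the other factor left out 176, and leaving out 1 library 25 to 263. The platform difference gave 0 genes in edgeR at a mean of 300 counts (343 with an unadjusted p under 0.05), 10 at 50 counts, 18 with DESeq2 size factors, 27 with total counts and 25 with no filter. Limma-voom gave 87 and DESeq2 38. Leaving out the other factor gave 0 in edgeR (388 with an unadjusted p under 0.05), and leaving out 1 library 0 to 27; the cause of these losses was not tested. Of 537 gene ratios, total counts left 531 at the same call and DESeq2 size factors 536, and of list medians 5 moved and 53 stayed at 50 counts, and 7 moved and 33 stayed at a mean of 300 counts. Fits without 1 library left out the other factor and took the lone library to vary like the rest.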

Other observations

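All tests of the hypotheses below were chosen only after the result was seen, and 4 gene lists were tried. Medians are also given without genes that were in a fixed list or already named. That does not make a list independent of these data.

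Genes of fatty acid synthesis were also lower after the switch to differentiation medium. The 21 tested genes had median log2 ratios of -1.01 on PUCL and -0.41 on PUCL@CNT1, and 13 were lower and 1 higher on both platforms by sign, and 5 lower and 0 higher by the size rule. The median of the mean ratios, -0.77, lay at percentile 0.04 among random lists, and without the 1 gene already listed or named it was -0.87 (percentile 0). Scd2, a desaturase, had -1.25 and -0.68 (edgeR adjusted p 0.000323), Elovl6, an elongase, -1.82 and -1.13 (0.00176), and Acsl3, which activates fatty acids, -1.29 and -1.10 (0.00114), and 8 of 9 other tests kept each call. Outside the list, Acly, which makes cytosolic acetyl-CoA, had -1.31 and -1.26 (adjusted p 1.12e-06). Fixed lists often lay far out, so the percentile of 0.04 is limited evidence. It may reflect lower SREBP activity in differentiation medium, as lipid supplied by that medium could bring about. Differentiation medium without lipid, or a further 1.5 d in maintenance medium, would test it.

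Glucocorticoid-responsive genes were higher after the switch. Their 19 tested members had medians of 0.22 and 0.79, with 9 higher and 3 lower on both platforms by sign, and 3 higher and 0 lower by the size rule. The median of the mean ratios, 0.50, lay at percentile 98.8, and without the 2 genes already listed or named it was 1.30 (percentile 100). Klf9 had 1.11 and 1.61 (edgeR adjusted p 0.000644), Tsc22d3, the leucine zipper gene induced by glucocorticoids, 2.37 and 1.56 (0.0297), and Cebpd 0.98 and 1.71 (0.0298), while Fkbp5, a standard target, had -0.14 and -0.21 (0.951). Other tests kept the call of Klf9 in 8 of 9, Cebpd in 3 of 9 and Tsc22d3 in 2 of 8. Given how often fixed lists lay far out, the percentile of 98.8 is weak evidence for a hormone effect. It may reflect corticosterone in the B-27 supplement, but Fkbp5 did not follow. A receptor antagonist in differentiation medium would test this.

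Thyroid hormone-responsive genes were higher too, beside the hormone-binding Crym. The 15 tested members had medians of 0.49 and 0.74, with 7 higher and 2 lower on both platforms by sign, and 2 higher and 2 lower by the size rule. The median of the mean ratios was 0.75 (percentile 99.8), and without the 3 genes already listed or named also 0.75 (percentile 98.9). The percentile of 99.8 has the same limit, and the size rule gave as many members lower as higher. It may reflect thyroid hormone in the supplement, though Klf9 is in this list and the glucocorticoid list. Differentiation medium without the hormone would test it.

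Retinoid-responsive genes had medians of 0.60 on PUCL and 0.12 on PUCL@CNT1 over 12 tested members, with 5 higher and 3 lower on both platforms by sign, and 1 higher and 1 lower by the size rule. The median of the mean ratios was 0.74, and its percentile of 91.3 leaves open whether retinoid signalling changed.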
